A study of Mus musculus with 2 samples.

How the data were processed

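Cells sorted from Foxp3Cre-YFP mice on the C57BL/6 background were profiled by droplet single-cell RNA sequencing with the 10x Chromium 3' chemistry, in which each transcript is read from its 3' end and counted once through a unique molecular identifier (UMI). In these mice the Foxp3 locus, which encodes the lineage transcription factor of regulatory T cells (Treg cells), drives Cre recombinase and yellow fluorescent protein. Per the labels there were 2 groups of 1 library each: lymph node of unchallenged mice, and B16 melanoma taken at day 14. The labels say that the cells were sorted but do not name the gate, and the number of mice per library is not given in the sources used here. With 1 library per group there is no replicate check, so no test between the tissues was made and no p-value is given.

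The deposited values are raw UMI counts per gene and barcode, whole numbers with no normalization, in 1 unfiltered matrix per library of 27998 genes by 737280 barcodes. Per the submitters' processing notes, Cell Ranger was used with the mm10 build; its version and the annotation are not given in the sources used here. The lymph node matrix held 14000036 UMIs on 153212 barcodes and the tumour matrix 23618037 UMIs on 193946 barcodes. Gene names were taken from the deposited gene lists, and symbols shared by several genes were kept apart by their identifiers. The lists hold no entry for the reporter, and lack immunoglobulin constant and T cell receptor genes of the marker lists. Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 denotes, in which 27722 of the 27998 identifiers were found.

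A barcode was called a cell when its UMI total reached 10% of the 99th percentile of the top 3000 barcodes of its library, which gave thresholds of 1811 UMIs in lymph node and 3834 UMIs in tumour. It also needed at least 200 genes and at most 10% mitochondrial UMIs. Of 2226 and 1489 barcodes called, 13 and 14 exceeded the mitochondrial limit. The cells of both libraries were clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6), and a cluster with at least 3 markers of 1 other cell class among its 10 leading genes was left out. The marker lists were fixed before the data were examined and covered Treg cells, conventional CD4 T cells, CD8 T cells, gamma-delta T cells, NK cells and innate lymphoid cells, B cells, macrophages and monocytes, dendritic cells, neutrophils and mast cells, B16 melanoma, fibroblasts and stroma, endothelium, and erythroid cells and platelets. One step was added after the clusters were seen: the CD8 T cell name was refused where a cluster held no more Cd8a than Cd4. It kept 1 cluster of 13 lymph node and 1036 tumour cells, which has Ccl5, Gzmb and Nkg7 among its leading genes, and values without that cluster are given in the closing section. The retained cells are called sorted T cells here. Doublets were kept. Scrublet called 5 of 2203 lymph node cells (0.227%) and 5 of 1459 tumour cells (0.343%), a share so low that the caller is taken not to have worked.

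Raw counts were summed over the retained cells of each library and divided by their total and given as CPM, the usual scaled unit of counts. Cells with more UMIs thus weigh more in these sums. A joint cluster of 381 tumour cells led by mitotic genes had a median of 19195 UMIs, against 7179 in the cluster of 1036. A ratio carries the exact conditional-binomial 95% interval of 2 Poisson counts, a single sum the exact Poisson interval, and a share of cells the Clopper-Pearson 95% interval. Beside a share of 0 stands the limit that 3 cells of the total would give, or for the few background cells the upper bound of the interval. These intervals cover counting error only, not differences between mice, sorts or libraries. Those of ratios and sums treat every UMI as independent and leave out variation between cells as well. Where 1 library had no UMI, the ratio was set against a floor of 3 counts over the group and is written as at least that fold. No fold is given where both libraries held 3 UMIs or fewer. Genes with at least 50 UMIs over both libraries entered the counts of genes at least 2-fold apart. For each of 20 gene lists fixed before the data were examined, the members with at least 20 UMIs were used: their median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries only.

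Genes were named by a rule fixed before the data were examined: 16 genes of Treg biology whatever their values, the 12 genes with the largest ratio each way by the interval bound nearest to 1, up to 4 members of each list by the same bound, and up to 2 genes of each marker list. Mitochondrial, ribosomal, haemoglobin, antigen receptor and clone-named genes were left out of the ranking. The same ranking gave 10 genes each way between classes of tumour cells.

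To compare shares of cells with a UMI, each cell was thinned at random to 2288 UMIs, the lower of the 2 libraries' 10th percentiles. This left out 220 of the 2203 lymph node cells and none of the 1459 tumour cells. Tumour cells were also clustered by themselves without Il10, Ebi3 and Il12a, and grouped by detection of an Il10 UMI only, an Ebi3 UMI only, both or neither. Free RNA was profiled in barcodes of 1 to 10 UMIs and, as this proved sparse, of 11 to 100 UMIs. By the melanoma and haemoglobin transcripts in the barcodes of 11 to 100 UMIs, free RNA would account for 2.39% of the lymph node and 2.68% of the tumour population's UMIs. The lymph node figure is weak, as it rests on 5 such UMIs in the population and 51 in the barcodes. The tumour figure rests on 546 and 4580. Barcodes of tumour cells held a mean of 11.6 UMIs in the lymph node library against 3.73 elsewhere, an excess of reads that may have crossed between libraries of 0.0825% of its UMIs, and 1 barcode was called in both libraries against 4.43 by chance.

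The ratio step was tested on simulated counts with known changes. These were Poisson draws of the summed counts with no variation between cells, so the coverage checks the calculation of the intervals only. Between tumour and lymph node (10329 genes of all called cells), 95 of 95 genes changed 4-fold and 97 of 98 changed 3-fold came out at least 2-fold apart, with 9 of 10136 unchanged genes wrongly higher and 4 wrongly lower; the intervals covered the true ratio for 95.4% of genes. Between tumour cells with Il10 only and Ebi3 only (8337 genes of all called tumour cells, melanoma-like cells included), 97 of 97 and 94 of 99 were recovered. Coverage was 95.9%, but 14 of 8141 unchanged genes came out at least 2-fold higher and 140 at least 2-fold lower.

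Alternatives covered cell calling, the mitochondrial limit, the population, scaling (median-of-ratios and edgeR TMM factors), equal weight per cell, thinning, free RNA, doublets, cycling cells, count filters and clustering resolution; their effects are in the closing section. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and edgeR 4.0.16 for the TMM factors.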

Results

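The data are UMI counts from 1 lymph node library of unchallenged Foxp3Cre-YFP mice and 1 library from day 14 B16 tumours, a transplanted melanoma of C57BL/6 mice. The series title places the comparison in a study of Treg cells that make the inhibitory cytokines IL-10 and IL-35, the latter a dimer of the Ebi3 and Il12a products, and of exhausted T cells in tumours. After filtering, 2203 lymph node and 1459 tumour cells remained, with 10683953 and 16739777 UMIs in total, which is 76.3% and 70.9% of their libraries. The tumour cells were deeper and more complex, at medians of 8771 UMIs and 2444 genes per cell against 4103 UMIs and 1335 genes. The median mitochondrial share was 1.39% in tumour and 2.67% in lymph node. No comparison between the tissues has replicates, and intervals cover counting error only.

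The retained cells held T cell transcripts and the Treg transcript Ikzf2 in both tissues. At equal depth a UMI of Cd3e, a subunit of the T cell receptor complex, was found in 71.5% of lymph node and 73.5% of tumour cells, and one of Ikzf2, which encodes the Treg transcription factor Helios, in 61.7% and 85.7%. Cd4 was detected in 23.9% and 38.7% of cells. Cd8a was detected in no cell of either library, 0 of 1983 and 0 of 1459, which allows shares with a UMI of up to 0.151% and 0.206%, while Cd8b1 was detected in 3.68% and 4.52%. Joint clustering parted the tissues almost completely. Lymph node cells formed a cluster of 1339 cells led by Bcl2, Igfbp4, Satb1 and Ccr7 and one of 757 cells led by Tbc1d4, Nrp1 and Cd83, each with 9 tumour cells. Tumour cells formed a cluster of 1036 led by Ccl5, Gzmb, Ifngr1 and Tnfrsf9, with 13 lymph node cells and with 3 CD8 T cell markers and 0 Treg markers among its 10 leading genes, and one of 381 led by mitotic genes, with 1. Leading genes rank a cluster against the mean of the others, so markers shared between clusters would not lead. At full depth the cluster with CD8 T cell markers held Cd4 in 80.4% of cells, Ikzf2 in 96.8%, Ctla4 in 88.8% and Cd8a in 0%. An interferon-response cluster led by Ifit1, Ifit3 and Isg15 held 40 lymph node and 24 tumour cells.

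Tumour T cells held less of the transcripts typical of resting, recirculating T cells than lymph node T cells, and more of those of glycolysis, proliferation and suppressive mediators. All 13 measured genes of naive and central T cells were at least 2-fold lower in tumour, with a median log2 ratio of -3.61, below all of the 10000 matched random lists. Granzyme B (Gzmb), Il10 and the chemokine gene Ccl4 were 75-fold (62.9 to 90.2), 51.3-fold (29.2 to 99.7) and 451-fold (238 to 987) higher. Glycolysis genes had a median log2 ratio of 2.18 and proliferation genes 1.87. The core Treg genes stood apart from this, with a median log2 ratio of -0.07, though this ranged from -0.74 without the cluster with CD8 T cell markers to 0.23 without cells with 3 or more mitotic UMIs. In all, 1342 of 10005 genes were at least 2-fold higher in tumour and 766 at least 2-fold lower, by the ratio alone; for 905 and 413 of them the whole counting interval lay beyond 2-fold. The median log2 ratio over these genes was 0.14, and TMM scaling would move every log2 ratio by -0.10 (-0.104), which reverses none of the gene ratios given below.

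**Figure D1:**
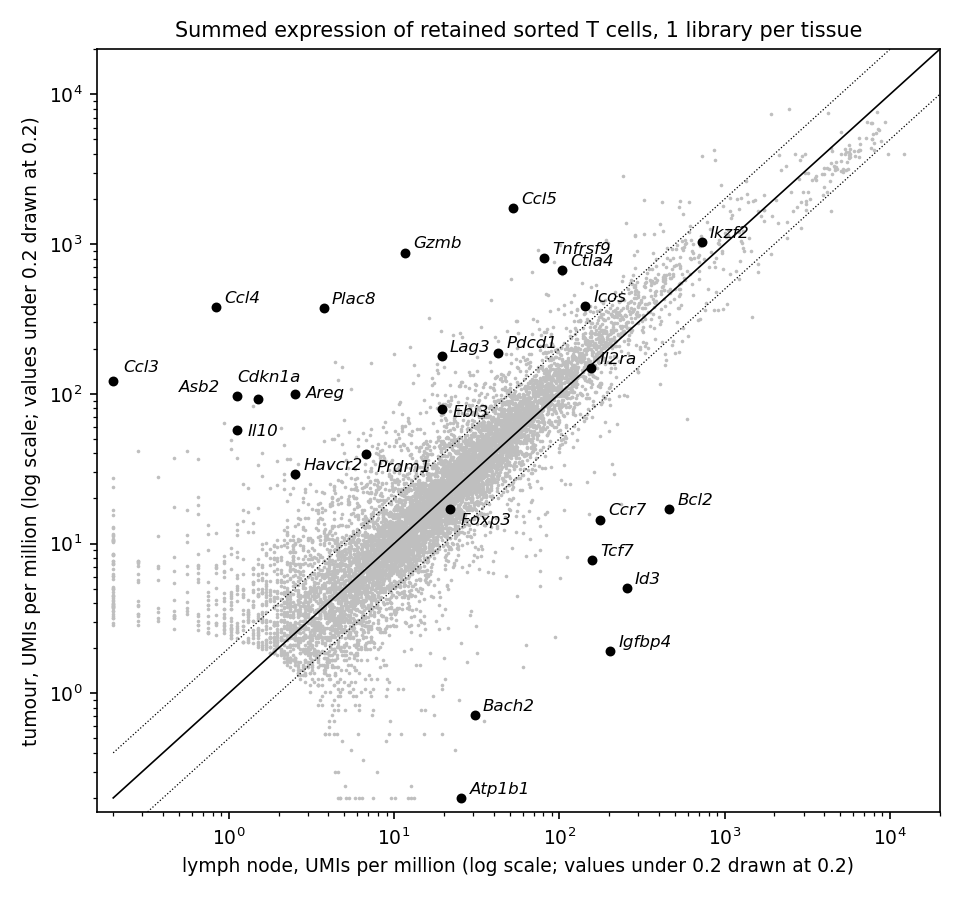
Each grey point is a gene with at least 50 UMIs over both libraries, placed by its CPM in the lymph node (x) and tumour (y) libraries on log scales, with values under 0.2 drawn at 0.2; black points are named genes, the solid line marks equal expression and the dotted lines 2-fold differences. Il10, Gzmb, Ccl3 and Ccl4 lie far above the lines, Igfbp4, Id3 and Bach2 far below, and Foxp3 and Il2ra near the line of equal expression.

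Both cytokine genes of the series title were higher in tumour, to different degrees. Il10 (ENSMUSG00000016529; mm10 chromosome 1, 131019845 to 131024974, plus strand) had 12 UMIs in lymph node and 965 in tumour, 1.12 against 57.6 CPM. Ebi3 (ENSMUSG00000003206; chromosome 17, 55952640 to 55957022, plus strand), the subunit that IL-35 shares with IL-27, had 209 and 1325 UMIs and was 4.05-fold higher (3.49 to 4.70). Il12a (ENSMUSG00000027776; chromosome 3, 68690644 to 68698547, plus strand), the other IL-35 subunit, had 0 UMIs in lymph node and 1 in tumour, so that the IL-35 pair was not detectable at this depth. Prdm1, which encodes the effector T cell regulator Blimp-1, was 5.92-fold higher (4.64 to 7.66). Among the 11 measured suppressive mediators 8 were at least 2-fold higher, 0 lower and 3 between (median log2 2.42, percentile 100; 1.71 in cells with a Foxp3 UMI and 3.22 without the 5% of cells with most UMIs). They included Areg, an epidermal growth factor family ligand, at 39.4-fold (27.0 to 59.9) and Fgl2, a secreted suppressor of T cells, at 11.9-fold (10.0 to 14.2).

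The Treg identity list had 3 members at least 2-fold higher, 2 lower and 8 between, and its median lay at percentile 2.33 of the random lists. Foxp3 (ENSMUSG00000039521; chromosome X, 7573644 to 7595245, plus strand) had 234 lymph node and 286 tumour UMIs and was 1.28-fold lower in tumour (1.07 to 1.53), a small difference that did not keep its direction when every cell was thinned to equal depth (log2 0.09). Il2ra, the high-affinity subunit of the IL-2 receptor, was 1.05-fold lower with an interval that includes 1 (0.987 to 1.12), and Ikzf2 was 1.42-fold higher (1.39 to 1.46). The higher members were Ctla4, an inhibitory receptor central to Treg suppression, at 6.42-fold (6.04 to 6.84), the TNF receptor family gene Tnfrsf18 (GITR) at 3.61-fold (3.48 to 3.74) and Il2rb at 2.36-fold (2.23 to 2.49). The largest difference went the other way: Gpr83, a receptor typical of resting Treg cells, was 29.9-fold lower (21.3 to 43.3).

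Inhibitory receptor genes, of a kind linked to T cell exhaustion, were mostly higher in tumour, which by itself does not show exhaustion. The inhibitory receptor list of 12 genes also holds the ectoenzyme gene Entpd1 and the transcription factor gene Tox. Of these 12 genes 8 were at least 2-fold higher, 3 lower (Cd160, Btla and Cd200) and 1, Tox, between, at log2 -0.59 (list median log2 1.62, percentile 100). Havcr2 (TIM-3) was 11.5-fold higher (7.78 to 17.6), Lag3 9.18-fold (7.97 to 10.6), Pdcd1 (PD-1) 4.42-fold (4.01 to 4.89) and Tigit 3.78-fold (2.46 to 6.03), while Cd160 was 6.02-fold lower (4.05 to 9.19). The effector Treg list had 12 members higher, 1 lower and 3 between (median log2 1.79, percentile 100). Its examples are the transcription factor gene Bhlhe40 at 18.5-fold (15.2 to 22.7), Id2, an inhibitor of E proteins, at 11.5-fold (10.5 to 12.6), Nfil3 at 10.5-fold (8.00 to 13.9) and the receptor gene Klrg1 at 6.72-fold (5.76 to 7.87). The costimulatory receptor gene Icos was 2.71-fold higher (2.56 to 2.87). In the TNF receptor superfamily 4 members were higher, 1 lower and 4 between (median log2 0.85, percentile 98.6). Tnfrsf9 (4-1BB) was 9.95-fold higher (9.28 to 10.7) and Tnfrsf4 (OX40) 3.33-fold (3.23 to 3.45), and Tnfrsf25 was 7.63-fold lower (6.34 to 9.23).

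Genes that keep T cells recirculating and quiescent were lower in tumour. Ccr7, a chemokine receptor gene that directs entry into lymph nodes, was 12.2-fold lower (10.7 to 14.0). The transcription factor genes Tcf7 and Bach2, both of which restrain effector differentiation, were 20.3-fold (17.0 to 24.4) and 42.8-fold (24.2 to 83.7) lower, and the survival gene Bcl2 26.9-fold (23.8 to 30.4). The chemokine receptor and homing list moved both ways, with 6 members at least 2-fold higher, 6 lower and 5 between (median log2 0.13, percentile 33.1). Ccr2, a receptor gene for inflammatory chemokines, was 13.7-fold higher (11.9 to 15.8). Ccr10 and Ccr9, which direct cells to skin and gut, were 24.3-fold (13.6 to 47.9) and at least 28.7-fold lower.

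Among T cell cytokines 7 measured genes were at least 2-fold higher, 2 lower and 4 between (median log2 1.81, percentile 100), but the median depended on weakly counted members and was 0.05 among those with at least 100 UMIs. Besides Il10 they were led by inflammatory chemokines: Ccl3, with no lymph node UMI, was at least 436-fold higher, and Ccl5 was 33.3-fold higher (30.7 to 36.3). Of the lineage transcription factors 4 were higher, 1 lower and 4 between (median log2 0.89, percentile 98.4; 0.25 without the cluster with CD8 T cell markers). Tbx21, which encodes the type 1 regulator T-bet, was 16.4-fold higher (10.9 to 25.8), Rora 3.24-fold (2.90 to 3.64) and Stat3 2.49-fold (2.29 to 2.71), whereas Bcl6, the regulator of follicular T cells, was 3.70-fold lower (1.77 to 8.30). Early targets of T cell receptor signalling had 5 members higher, 1 lower and 7 between (median log2 0.69, percentile 98.5). Nr4a2 was 13.6-fold higher (8.98 to 21.7), Tnfaip3, a brake on NF-kappaB, 7.66-fold (6.27 to 9.44) and Nr4a1 4.34-fold (3.78 to 4.99). Genes known to respond to tissue dissociation and stress were higher as well, with 10 higher, 0 lower and 8 between (median log2 1.34, percentile 100). In this list Ier3 was 31.1-fold (14.9 to 77.9), the heat shock gene Hspa1a 21.1-fold (13.9 to 33.4), Fos 13.6-fold (10.3 to 18.2) and Dusp1 9.37-fold (8.29 to 10.6) higher. Any difference in how the tissues were prepared cannot be separated from the tissue here, for this list or for the receptor signalling list.

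Glycolysis, hypoxia and sterol genes were higher as groups. All but 1 of the 16 glycolysis genes were at least 2-fold higher (15 higher, 0 lower, 1 between, percentile 100), among them the lactate exporter gene Slc16a3 at 31.0-fold (23.5 to 41.6), Tpi1 at 12.4-fold (11.5 to 13.3) and Aldoa at 6.01-fold (5.80 to 6.23). In the hypoxia response 9 genes were higher, 0 lower and 1 between (median log2 1.91, percentile 100). Bnip3, which acts in mitophagy, was 20.5-fold (15.5 to 27.7), the lipid droplet gene Hilpda 19.7-fold (17.0 to 23.1) and Hif1a, the oxygen-regulated transcription factor gene, 5.46-fold (5.02 to 5.95) higher. Sterol and fatty acid genes had 11 members higher, 0 lower and 4 between (median log2 2.07, percentile 100). The cholesterol synthesis genes Idi1, Sqle and Cyp51 were 7.42-fold (6.01 to 9.26), 7.32-fold (5.67 to 9.58) and 6.57-fold (5.45 to 8.00) higher. Nuclear-encoded respiration genes differed less, with 1 higher, 0 lower and 18 between (median log2 0.47, percentile 61.8). The 1 higher gene was Cycs, cytochrome c, at 2.30-fold (2.18 to 2.43).

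Proliferation genes had 22 members at least 2-fold higher, 0 lower and 3 between (percentile 100); their median ranged from 1.07 without cells with 3 or more mitotic UMIs to 3.61 without the 5% of cells with most UMIs. Ube2c and Ccnb1, which act in mitosis, were 5.60-fold (5.14 to 6.11) and 5.15-fold (4.35 to 6.13) higher and Tk1, of thymidine salvage, 4.85-fold (4.21 to 5.61). At equal depth a UMI of the proliferation marker gene Mki67 was found in 13.3% of tumour and 1.71% of lymph node cells. Of the interferon-stimulated genes 16 were higher, 0 lower and 3 between (median log2 1.68, percentile 100): Ly6a, also an activation marker of T cells, was 11.7-fold (11.3 to 12.2), Mx1 8.54-fold (5.63 to 13.5), Isg20 5.40-fold (4.93 to 5.93) and Isg15 5.37-fold (5.02 to 5.76) higher. MHC class I presentation had 1 higher, 0 lower and 10 between (median log2 0.74, percentile 96.9), with the peptide transporter gene Tap1 at 2.83-fold (2.66 to 3.0). TGF-beta signalling had 1 higher, 2 lower and 8 between (median log2 -0.02, percentile 14.2). There Itgav, an integrin subunit that activates TGF-beta, was 5.64-fold higher (4.70 to 6.81) and the receptor gene Tgfbr1 3.94-fold lower (3.42 to 4.54). IL-2 and common gamma chain signalling had 3 higher, 1 lower and 10 between (median log2 -0.00, percentile 2.19). Its kinase gene Jak3 was 2.77-fold (2.35 to 3.29) and its feedback gene Cish 2.33-fold (2.14 to 2.53) higher.

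**Figure D2:**
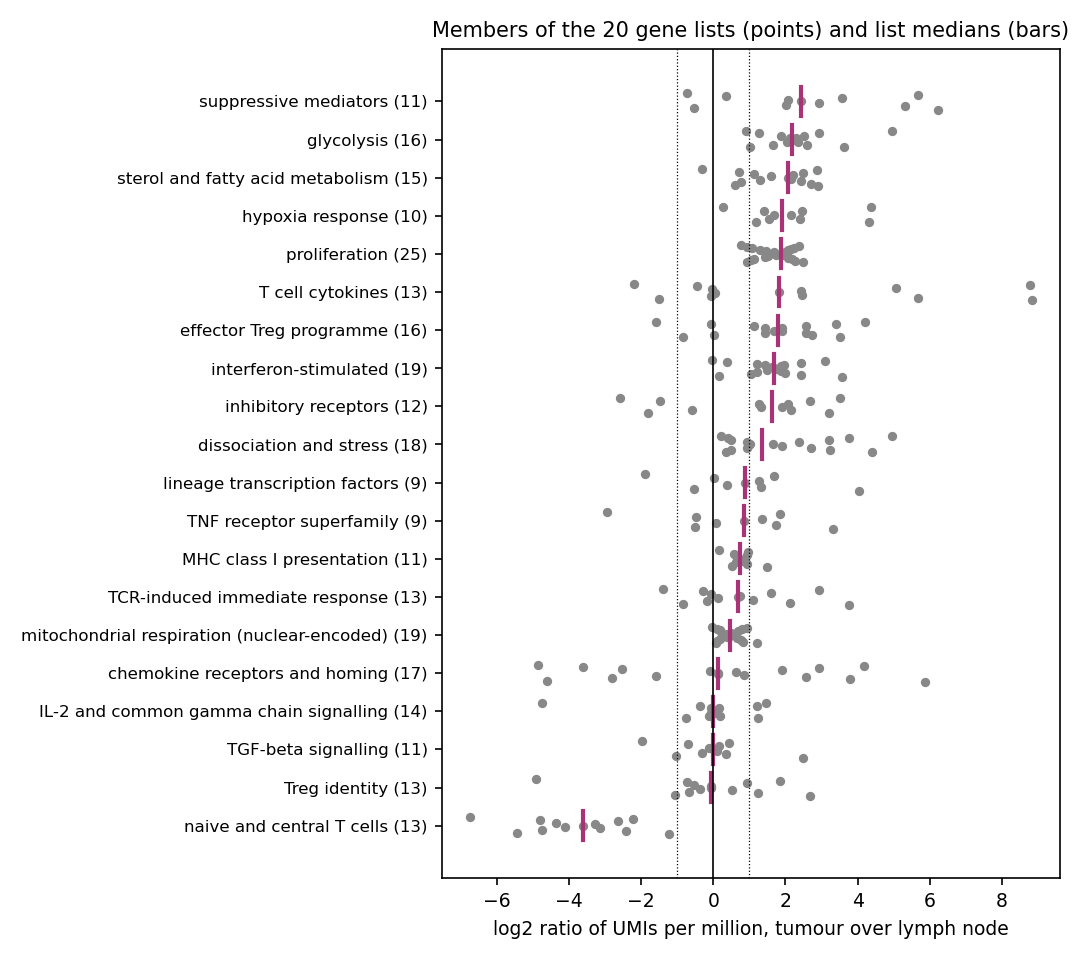
Each point is a measured member of a gene list (number of measured members in parentheses) at its log2 ratio of CPM, tumour over lymph node, 1 library each; bars are list medians, the solid line is 0 and the dotted lines mark 2-fold. The naive and central T cell list lies wholly below the lower dotted line with a median of -3.61, and suppressive mediators and glycolysis have the highest medians, 2.42 and 2.18.

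The genes with the largest differences were in part outside the lists. Higher in tumour, besides Ccl4, Ccl3 and Gzmb, were the inhibitory receptor gene Lilrb4a at 148-fold (50.5 to 720), Plac8 at 99.8-fold (73.2 to 140), Ccdc184 at no less than 97.4-fold, the ubiquitin ligase subunit gene Asb2 at 85.4-fold (48.8 to 166), the cell cycle inhibitor gene Cdkn1a (p21) at 62.1-fold (38.1 to 109) and Cables1 at no less than 46.2-fold. Lower in tumour were Atp1b1, a sodium pump subunit gene, at 213-fold (58.4 to 1768), Cnn3 at 107-fold (28.9 to 889), Igfbp4, which encodes a binding protein of insulin-like growth factors, at 106-fold (74.7 to 155) and Arhgap20 at 102-fold (27.6 to 850). They were followed by Wnt10a at 73.6-fold (24.7 to 361), Gata1 at 55.7-fold (26.7 to 140), St8sia6 at 53.4-fold (29.5 to 108), Tmem108 at no less than 53.3-fold, Id3, an inhibitor of E proteins, at 50.9-fold (41.0 to 64.0), Capn3 at 40.3-fold (27.0 to 62.7) and Nsg2 at 39.2-fold (28.6 to 55.2).

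The remaining 3 of the 12 genes that ranked highest were macrophage transcripts: Ccl12, Wfdc17 and the complement gene C1qb were at least 85.5-fold, 59.6-fold and 55.5-fold higher in tumour, with no lymph node UMI. In these 3 cases 3 of the 1459 tumour cells held 94.8%, 95% and 93.1% of the UMIs. Without these cells the bounds were 4.48-fold for Ccl12, 2.99-fold for Wfdc17 and 3.84-fold for C1qb, and Tubb6 at 67.1-fold (36.3 to 140) and Il12rb2, an IL-12 receptor subunit gene, at least 40.8-fold higher were among the genes that took their places. Lilrb4a was then 140-fold higher (47.8 to 682).

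Marker lists of other cell types were compared in the same summed counts, as levels in lymph node and tumour. The CD8 T cell list stood at 183 and 3625 CPM, mostly from Ccl5 and Nkg7, a cytotoxic granule gene that was 9.80-fold higher (9.21 to 10.4), with no Cd8a UMI. Conventional CD4 T cell markers stood at 428 and 243 CPM and Treg markers at 3328 and 5904 CPM. The conventional list mixes genes that went opposite ways, led by Igfbp4 (202 and 1.91 CPM) and Bhlhe40 (9.92 and 184 CPM). The dendritic list stood at 380 and 1184 CPM, led by the interferon-responsive gene Bst2, 4.0-fold higher (3.79 to 4.23), and by Cd74, the MHC class II invariant chain gene, 2.67-fold higher (2.51 to 2.83); the 3 macrophage-positive cells held 10.9% of the tumour's Cd74 UMIs. The B cell list, which also holds Cd74, stood at 146 and 344 CPM, while the B cell receptor gene Cd79b was 1.82-fold lower (1.45 to 2.29). Macrophage and monocyte markers stood at 330 and 476 CPM, led by Ctss, which stood at 322 and 278 CPM and changed direction without mitotic cells (log2 0.19), and by Ly6c2, 27.1-fold higher (20.4 to 36.7). B16 melanoma markers stood at 1.31 and 47.5 CPM, and a UMI of Tyrp1 was found in 10.8% of tumour cells and in none of the lymph node cells. NK cell and innate lymphoid markers stood at 1.31 and 30.7 CPM, led by Fcer1g, with 94.0% of its tumour UMIs in the 3 macrophage-positive cells. Endothelial markers stood at 70.5 and 24.0 CPM, mostly from Pecam1 (68.3 and 19.5 CPM), which T cells also express, and erythroid and platelet markers at 0.374 and 10.9 CPM, the latter from Pf4, of whose UMIs the same 3 cells held 92.7%. Fibroblast markers stood at 0.842 and 1.43 CPM, neutrophil and mast cell markers at 0.842 and 0.299 CPM, and gamma-delta T cell markers at 0 and 0.0597 CPM.

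The next comparison asked in how many cells the transcripts were found. At an equal 2288 UMIs per cell, an Il10 UMI was present in 0.303% of lymph node (0.111 to 0.657) and 7.47% of tumour cells (6.17 to 8.94), and an Ebi3 UMI in 3.78% (2.99 to 4.72) and 16.9% (15 to 18.9). The tumour Il10 share was 4.49% without the cluster with CD8 T cell markers, and the lymph node share 0.105% without cells with 3 or more mitotic UMIs. The latter rests on few cells: with that filter applied after thinning, 6 of 1928 lymph node cells held an Il10 UMI. Without thinning the tumour shares were 16% for Il10 and 49.5% for Ebi3, and the lymph node shares 0.409% and 6.95%. An Il12a UMI was found in 0 of 1983 lymph node cells, which allows a share of up to 0.151%, and in 1 of 1459 tumour cells, 0.0685%. Prdm1 was found in 1.31% of lymph node (0.858 to 1.92) and 8.57% of tumour cells (7.18 to 10.1). Foxp3 shares were close, 4.54% (3.67 to 5.55) and 5.00% (3.94 to 6.25), and unthinned 9.58% and 16.7%. As background, no Il10 or Ebi3 UMI was found in the 16 melanoma-like tumour cells or the 10 B-like lymph node cells after the same thinning, with upper 95% bounds of 20.6% and 30.8%. At their full depth, a median of 68944.5 UMIs, 6.25% of the melanoma-like cells held an Il10 UMI and 43.8% an Ebi3 UMI, at 0.802 and 6.41 CPM against 57.6 and 79.2 CPM in the retained tumour cells. Of the 10 B-like cells, at a median of 3398.5 UMIs, 1 held an Ebi3 UMI. Free RNA would give 0.418% of thinned tumour cells an Il10 UMI and 0.460% an Ebi3 UMI.

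The named inhibitory receptors and Icos were found in more tumour than lymph node cells at equal depth. Ctla4 was detected in 65.4% (62.9 to 67.8) against 18.6% (16.9 to 20.3), Icos in 54.5% (51.9 to 57.1) against 19.1% (17.4 to 20.9), Pdcd1 in 31.5% (29.1 to 33.9) against 7.06% (5.97 to 8.28) and Lag3 in 26.5% (24.3 to 28.9) against 3.38% (2.63 to 4.27). Havcr2 and Tigit, at lower levels, were detected in 6.10% (4.93 to 7.45) and 2.19% (1.5 to 3.08) of tumour cells against 0.303% and 0.252%. Unthinned tumour and lymph node shares were 91.2% and 29.1% for Ctla4, 89.2% and 28.2% for Icos, 64.5% and 13.2% for Pdcd1, 48.9% and 5.72% for Lag3, 23.4% and 0.862% for Havcr2, 9.60% and 0.953% for Tigit, and 30.2% and 2.86% for Prdm1. A Gzmb UMI was found in 45.1% of tumour and 0.656% of lymph node cells. Among the 16 thinned melanoma-like cells 4 held a Ctla4 UMI and 1 a Gzmb UMI, and free RNA would give 5.35% and 4.67% of thinned tumour cells one. At full depth 81.2% of the melanoma-like cells held a UMI of either gene, at 48.9 CPM for Ctla4 and 27.3 CPM for Gzmb, against 670 and 878 CPM in the retained tumour cells.

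**Figure D3:**
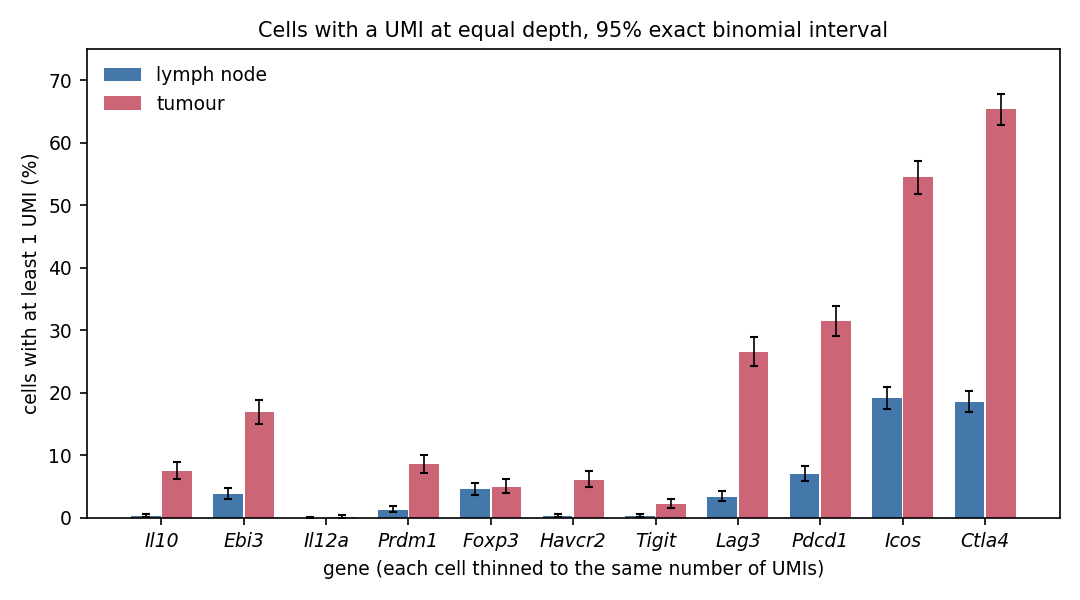
Bars are the percentage of cells with at least 1 UMI of each gene after every cell was thinned to 2288 UMIs, in 1983 lymph node (blue) and 1459 tumour cells (red), and error bars are 95% exact binomial intervals, which cover counting error only. Ctla4 reaches 65.4% of tumour cells against 18.6%, whereas the Foxp3 bars, 5.00% and 4.54%, overlap within their intervals.

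Whether Il10 and Ebi3 mark the same or separate tumour cells was asked by counting cells with both. At equal depth 18 tumour cells held both, against 18.4 expected from the separate shares, a ratio of 0.98 (0.582 to 1.54). Ebi3 was found in 16.5% of Il10-positive (10.1 to 24.8) and 16.9% of Il10-negative tumour cells. Without thinning 123 cells held both against 115 expected, a ratio of 1.07 (0.893 to 1.26). Among 244 tumour cells with a Foxp3 UMI 1 held both against 3.27 expected, a ratio of 0.31 with an interval that includes 1 (0.00774 to 1.69). In lymph node 1 cell held both, too few to compare. Neither an excess nor a lack of cells with both was detectable at this depth, and the interval leaves room for either.

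The tumour cells were then split by detection into 110 with Il10 only, 599 with Ebi3 only, 123 with both and 627 with neither. These are detection classes, not cell types, and they differ in depth, with median UMIs of 8470.5, 10654, 11528 and 7202. The intervals of their ratios pool the UMIs of a class and leave out variation between its cells, so they are too narrow for genes that vary between cells. The genes that ranked highest in cells with Il10 only over cells with Ebi3 only included chemokine, granzyme and receptor genes: Ccl4 was 4.63-fold (4.31 to 4.97), Lag3 3.73-fold (3.34 to 4.16), Ccl3 2.69-fold (2.35 to 3.07), Gzmb 2.20-fold (2.08 to 2.32), Areg 2.16-fold (1.84 to 2.52) and Ccr2 2.03-fold (1.84 to 2.25) higher. Also higher were Spp1, which encodes osteopontin, at 5.03-fold (3.34 to 7.51), Angptl2 at 3.09-fold (2.32 to 4.10), Sv2c at 2.81-fold (2.17 to 3.60) and Nfil3 at 2.32-fold (1.87 to 2.88). Ctla4 was 1.93-fold (1.81 to 2.05), Maf, a transcription factor gene that drives Il10, 1.62-fold (1.44 to 1.81) and Icos 1.57-fold (1.44 to 1.71) higher. The gene lists as wholes differed little, with 1 of 16 effector Treg genes (median log2 0.14), 2 of 8 suppressive mediators (0.40) and 1 of 10 inhibitory receptors (0.22) at least 2-fold higher with Il10 only. Prdm1, at 1.24-fold (0.912 to 1.67), and Havcr2, at 1.02-fold (0.693 to 1.47), had intervals that include 1. Prdm1 stood at 46.7 CPM with Il10 only, 37.6 with Ebi3 only, 54.0 with both and 37.4 with neither.

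By the ratio alone 71 of 8091 genes were at least 2-fold higher and 214 at least 2-fold lower with Il10 only than with Ebi3 only. Simulated counts with no difference gave 14 and 140 of 8141 genes, so counting error alone could give much of the lower count. The simulated counts followed all called tumour cells, melanoma-like cells included, so they are not matched to those of the retained cells. The simulation holds no variation between cells, so what exceeds it cannot be taken as a difference between the classes. In thinned cells the counts were 13 and 29 of 1934 genes, and without cells with 3 or more mitotic UMIs 28 and 96 of 4351. Unthinned cells with Ebi3 only also held more proliferation transcripts, 9802 against 7688 CPM, but the classes differ in depth. In thinned cells the log2 ratio of Mki67, Il10 only over Ebi3 only, changed sign from -0.32 to 0.65. The 10 genes that ranked lowest (Ccl12, Wfdc17, C1qb, Ccl2, Ccl6, H2-Aa, C1qa, Hmox1, Fcer1g and H2-Eb1) are macrophage or MHC class II genes. Their ranks rest on 2 macrophage-positive cells among the 599 with Ebi3 only, since without such cells none of them ranked among the 10 lowest. The list was then led by Penk, which encodes the enkephalin precursor, 4.10-fold lower with Il10 only (2.90 to 5.99), the chemokine gene Xcl1, at least 2.81-fold lower, and Tnfsf11 (RANKL), 6.46-fold lower (2.16 to 31.7). It also held Hmgn5 at 2.16-fold (1.59 to 3.0) and Il1r2, a decoy receptor gene for IL-1, at 2.04-fold lower (1.61 to 2.62).

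Within the tumour, clusters made without Il10, Ebi3 and Il12a all held both transcripts. At equal depth Il10 was found in 3.75% (1.39 to 7.98) to 11.3% (4.99 to 21) of the cells of the 6 clusters and Ebi3 in 12.5% (8.47 to 17.6) to 20.5% (15.3 to 26.5). At resolution 1.0 the highest Il10 share among 11 smaller clusters was 21.2% (12.1 to 33.0), in 66 cells. Macrophage genes such as Ccl12 and C1qb (307 CPM) are among the genes that lead that cluster. Its interval, picked as the highest of 11, lies above those of several other clusters of that resolution. An example is 4.19% (1.70 to 8.45) in 167 cells led by Klf2 and Tcf7. Il10 was itself a leading gene of another cluster there, of 290 cells, at 143 CPM. At the main resolution the lowest Il10 share was in cluster 5, 160 cells led by the central memory genes Klf2, Tcf7 and S1pr1, where Gzmb stood at 468 CPM. The highest Ebi3 share was in cluster 4, 215 cells led by interferon-response genes, where Gzmb stood at 2360 CPM. The largest cluster, of 549 cells, had Il10 in 9.47% (7.15 to 12.2); 3 macrophage-positive cells dominate the genes that lead it. Cycling cells formed cluster 2 (240 cells; replication genes such as Mcm2 and Pcna), cluster 3 (224 cells; Nusap1, Top2a) and cluster 6 (71 cells; Ccnb2, Cenpa), with Ebi3 in 14.2%, 12.5% and 12.7% of cells. At the main resolution the intervals of the 6 clusters overlap for both genes, but at resolution 1.0 those for Il10 do not all overlap. Within clusters, 18 cells with both transcripts stood against 19.0 expected, a ratio of 0.95.

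**Figure D4:**
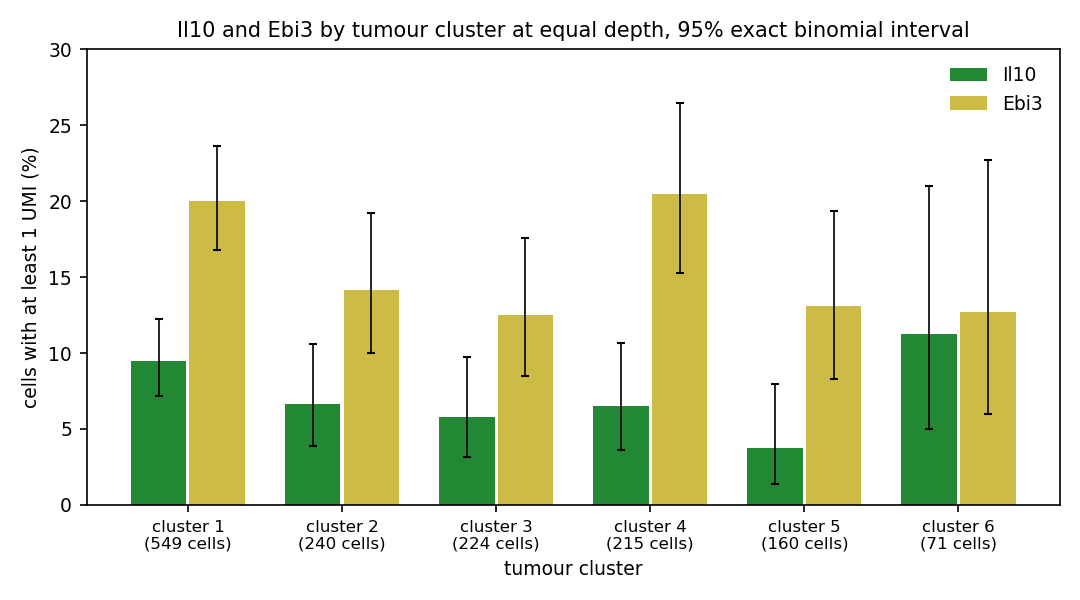
Bars are the percentage of tumour cells with at least 1 Il10 (green) or Ebi3 (yellow) UMI after thinning to 2288 UMIs, in 6 clusters made without these genes, and error bars are 95% exact binomial intervals, which cover counting error only. Il10 ranges from 3.75% in cluster 5 to 11.3% in cluster 6, whose intervals overlap, and Ebi3 from 12.5% to 20.5%.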

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

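The results of this part were seen in cells and barcodes outside the comparisons above, and no explanation of them was tested. The tumour library held 16 melanoma-like cells, led by Dct, Tyrp1, Pmel and Mlana, at a median of 68944.5 UMIs, where the lymph node library held none. The lymph node library held 10 B-like cells, led by Cd79a and Ms4a1, at a median of 3398.5 UMIs, where the tumour library held none. Both libraries are labelled as sorted cells. Tumour barcodes of 11 to 100 UMIs, taken as droplets without a cell, held the melanoma transcript Dct at 401 CPM, against 0.767 CPM in lymph node barcodes of that size and 8.36 CPM in the retained tumour cells.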

How the results depend on the processing

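With 1 library per tissue, depth and counting error are the only precision given here, and the intervals of ratios leave out variation between cells. Differences between mice, tissue preparations, sorts and runs cannot be separated from the tissue, and the gate is not named. No paired analysis was possible because each group has 1 library, and replicate 1 in both is a number only. Alternatives with cells excluded by CD8 T cell markers, macrophage transcripts or mitotic genes, and the free RNA profile of 11 to 100 UMIs, were chosen after seeing the data. Over all alternatives 496 values of the main results stayed within their interval (counts of genes within 1.5 times) and 35 moved beyond it. For list medians that interval is the spread of the median over the list's members, not counting error. It is often wide, from -0.52 to 5.68 for suppressive mediators, so a list median that stayed says little about its stability. The alternatives also include leaving out the Scrublet calls, only 5 cells per library. Of the single genes and receptor shares 1803 stayed, 599 moved and 4 at least 2-fold apart reversed. Differences under 2-fold changed sign in other places: 14 times for list medians, up to 0.23 for Treg identity, 0.17 for TGF-beta and 0.33 for IL-2 signalling, all without mitotic cells, and for single genes 16 times beyond and 6 times within their interval, among them Foxp3, at a log2 ratio of 0.09 in thinned cells and 0.12 without mitotic cells. The T cell cytokine median of 1.81 stayed within a wide interval but was 0.05 for members with at least 100 UMIs, 0.14 in thinned cells, 0.31 without mitotic cells and 0.82 with a lower UMI minimum per barcode, so no direction of that list as a whole is claimed. The planned exclusion of cells with 3 or more UMIs of the proliferation list left 192 lymph node and 3 tumour cells, since the list holds genes that most cells express; under a minimum of 50 cells set after this was seen it gave no values for expression, shares or classes, and 11 mitotic genes took its place. In thinned cells, used for co-detection, 175 tumour cells stayed under that number, 14 with Il10 and 38 with Ebi3.

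The values of the main results that moved, and the 4 reversals, follow. Except where stated, the cause was not tested. In the 211 lymph node and 244 tumour cells with a Foxp3 UMI, where C1qb, Fcer1g and Pf4 had too few UMIs, 730 genes were at least 2-fold higher and 264 lower, fewer by construction. There the log2 ratio was 4.74 for Il10 and 1.56 for Ebi3, the proliferation median 1.13, the Il10 and Ebi3 co-detection ratio 0.306 (0.00774 to 1.69) and the thinned lymph node Il10 share 0% (0 of 193 cells, which allows 1.55%; unthinned, 2 lymph node and 131 tumour UMIs give the ratio). With no count filter beyond 1 UMI the counts were 2047 and 1766, and with 200 UMIs 355 genes were lower, both by construction. Thinned cells gave 485 genes lower, a proliferation median of 2.42 and, between cells with Il10 only and Ebi3 only, 13 genes higher and 29 lower of 1934 (71 and 214 of 8091 in the main comparison). Weighting every cell equally gave a proliferation median of 2.30 and an Ebi3 log2 ratio of 2.34; without the 5% of cells with most UMIs they were 3.61 and 2.24. Unthinned shares, deeper by construction, were 6.95% and 49.5% for Ebi3 in lymph node and tumour and 16% for Il10 in tumour. At resolution 1.0, with 11 smaller clusters, the highest cluster shares were 21.2% for Il10 and 26.6% for Ebi3.

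Without clusters with 3 CD8 T cell markers (2190 lymph node and 423 tumour cells left), the Treg identity median was -0.74, the proliferation median 2.68, the Ebi3 log2 ratio 1.70, and the tumour shares 14.7% for Ebi3 and 4.49% for Il10; 381 of the tumour cells left belong to the mitotic cluster, by construction. Without cells with 3 or more mitotic UMIs (2114 and 691 left), the medians were 1.07 for proliferation, 1.06 for MHC class I and 2.22 for interferon-stimulated genes, the Ebi3 log2 ratio was 2.48, the lymph node Il10 share 0.105%, and between cells with Il10 only and Ebi3 only 28 genes were higher and 96 lower of 4351. That Il10 share rests on few cells, and with the filter applied after thinning 6 of 1928 lymph node cells held an Il10 UMI. The 4 reversals concern macrophage transcripts in that comparison: without macrophage-positive cells the log2 ratios were 0.17 for C1qa, 1.95 for Fcer1g and 0.44 for Hmox1, by construction, and without mitotic cells 0.44 for Hmox1.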

Other observations

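The tests on macrophage transcripts and on strictly separate Il10 and Ebi3 cells were chosen only after their result was seen, and those on Foxp3 and on co-detection under depth and cycling before. In the joint clustering a larger group of 1339 lymph node cells was led by genes of recirculating T cells (Bcl2, Ccr7, S1pr1, Lef1, Gpr83). A group of 757 lymph node cells was led by Tbc1d4, Nrp1, Cd83 and Izumo1r, the folate receptor 4 gene of Treg cells. These genes rank a cluster against the mean of all others, tumour clusters included, so they need not separate the lymph node groups from each other. Another group of 53 cells was led by cycling genes (Stmn1, Top2a, Mki67) together with Ccr10, the skin-homing receptor gene, and held no tumour cell.

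Among tumour cells, Mt2 and Mt1, which encode metallothioneins, were, relative to cells with neither transcript, 4.22-fold (3.12 to 5.69) and 3.16-fold (2.74 to 3.64) higher in cells with Il10 only, and 4.46-fold (3.43 to 5.82) and 3.80-fold (3.37 to 4.28) higher in cells with both transcripts; both genes are also among those that lead the melanoma-like cells. The chemokine gene Ccl1 was 11.3-fold (5.80 to 25.2) and Penk 4.58-fold (3.17 to 6.81) higher in cells with both than with Il10 only. In cells with Ebi3 only, set against cells with neither, macrophage genes such as Ccl2 and Lyz2 ranked highest through 2 macrophage-positive cells among the 599, and Klf2 was 2.08-fold (1.82 to 2.38), Tcf7 2.63-fold (1.77 to 3.95), Ccr7 1.86-fold (1.41 to 2.46), Lag3 1.64-fold (1.5 to 1.79) and Ccl5 1.51-fold (1.47 to 1.55) lower.

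Macrophage transcripts were among the genes most raised in the tumour population, through 3 cells. Free RNA is argued against: in the retained cells these transcripts stood at 146% of their level in barcodes of 11 to 100 UMIs, melanoma transcripts at 2.70%, 54.1 times apart. A T cell of called size beside a macrophage in all 3 cells is argued against as well. T cell transcripts in the 3 cells together stood at 5.88% (4.25 to 7.92) of their level in the other tumour cells. The smallest tumour cell in each would bring 14.5% and a median one 33.1%. Since the 3 cells were pooled, such a droplet among them is not excluded, nor is a T cell under the calling threshold. A first form of that test, any Cd3 UMI, was met by 3 of 3 cells but was replaced after its result was seen, because free RNA would give 5.72 of the 11 Cd3 UMIs. Macrophages called as cells remain a candidate explanation: 5 of 6 further macrophage genes stood over 10 times higher in these cells, Ctss being the exception.

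Few cells held a Foxp3 UMI in a sort from Foxp3 reporter mice. At equal depth 11 other Treg markers were summed in cells without and with a Foxp3 UMI. The level without was 0.860 times that with in tumour (0.814 to 0.910) and 0.902 times in lymph node (0.838 to 0.973). Both intervals lie under 1. A minority of Foxp3-positive cells among negative ones that largely lack these markers is argued against. Negative cells that hold these markers at a similar level cannot be excluded this way. Shallow sampling of 1 low level shared by the cells stays undecided: the share of cells with a UMI was 0.951 times the Poisson share in lymph node and 0.986 times in tumour, but at so low a level 80% of cells without the transcript would still give 0.909 and 0.904. Whether reads of the reporter allele escape the counted Foxp3 transcript was not tested, since the reporter has no entry in the gene list used here.

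Il10 and Ebi3 UMIs met in the same tumour cells about as often as independent detection gives. At equal depth the ratio was 0.979 (0.582 to 1.54), and in the 175 cells with under 3 proliferation UMIs it was 1.32 (0.360 to 3.31). In all thinned cells no departure from independence was seen, so that depth and cycling had nothing to explain, and neither test decides. With under 3 mitotic UMIs (1073 cells, chosen after the data were seen) the ratio was 1.03 (0.579 to 1.69), and in 244 cells with a Foxp3 UMI 0.306 (0.00774 to 1.69). Strictly separate Il10 and Ebi3 cells are argued against, since 16.5% (10.1 to 24.8) of Il10-positive cells held an Ebi3 UMI where free RNA would give 0.460%; a partial separation or overlap within these intervals stays open.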
